A study of Physcomitrium patens with 8 samples.

How the data were processed

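Gene expression was measured in protonemal colonies of the moss Physcomitrium patens on 8 custom Agilent 2-colour oligonucleotide arrays. Each array compared wild type (WT) with the atg5 line, a knockout of autophagy related gene 5 that per the labels cannot carry out autophagy, after the same treatment. There were 4 treatments with 2 arrays each, named biological replicates in the labels. In replicate 1 of every treatment WT carried Cy3 and atg5 carried Cy5, and in replicate 2 the dyes were exchanged. Hydration stands for colonies cultured for 7 days at 25 °C, and ABA for colonies then kept for 24 h on 50 µM abscisic acid. Dehydration stands for colonies dried over silica gel for 24 h, and Rehydration for dried colonies returned to fresh medium for 24 h. Each sample's labels give 200 ng of RNA per labelling and the series' text 400 ng, with no difference stated between arrays. The labels do not state whether the dried colonies had been on abscisic acid before drying.

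Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 9.5.3.1, whereas the submitters' processing notes name Agilent Feature Extraction 9.1. They hold spot intensities on a linear scale, as median pixel signals and local background medians per dye, together with background-subtracted and dye-normalized processed signals. Each array has 39733 spots, of which 38316 are gene spots of 38181 different probes, and 15 probes are printed 10 times each. The authors' deposited table of normalized intensities held, in each of its 16 columns, the processed signals of the scanner files at all 39733 spots, so it made no alternative of its own. The scanner files identify 2 slides, which coincide with the replicate number and thereby with the dye orientation, and 2 scans that follow the slides. A slide term is therefore the same as the replicate block. The deposited log10 ratios of Cy5 over Cy3, per the file headers computed by the same software, were exactly 0 at 24.5 to 39.7% of gene spots per array and were not used for tests.

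The median pixel signals took the place of the mean pixel signals named in the planned design, because the files give medians. Signals were corrected with normexp (offset of 50) against the local background medians and normalized within each array by loess, with control spots at weight 0 and left out afterwards. Spots with a non-uniformity or population outlier mark in either dye were left out, and spots of 1 probe were averaged. Probes were kept if well above background on both arrays of at least 1 of the 8 genotype and treatment groups, which left 19741 probes of 15499 loci. Loci were taken as the part of an identifier before its model version.

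The log2 ratio was turned to atg5 over WT on every array and fitted with limma's lmFit and eBayes over all 8 arrays, with 1 coefficient per treatment and no dye term. Differences of the atg5 effect between treatments were contrasts of the same fit. For 77 of the kept probes both spots of a treatment were left out, and 19664 probes were tested. Treatments were compared within a genotype in a separate-channel fit (Aquantile normalization between arrays, lmscFit with an estimated correlation of 0.679 between the channels of a spot). This fit takes no missing values and held 19143 probes. Counts are of probes with a Benjamini-Hochberg adjusted p under 0.05. Error is given as the standard error (SE) of the fitted log2 difference with n = 2 arrays per group. Dehydration against ABA was added as a comparison after the data were seen.

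The replicate numbers pair the arrays for the atg5 ratios. Deviations of same-numbered arrays from their treatment means correlated across probes at 0.27 to 0.531 in all 6 pairs of treatments, and these arrays share a slide and a dye orientation. The ratio fit reported here has no block, as planned, and so leaves this pairing out. Its counts with the replicate number as a block are given beside it. For the levels of single channels the same check gave 0.0349 to 0.105, not over 0.1 in every pair, so the separate-channel fit was kept without a block. Same-numbered channels of a genotype nonetheless share slide, scan and dye.

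The array files pair no identifier with a gene name or description. None of the array identifiers (0 matches) occurred in the given reference table of 27567 genes (assembly ASM5946719v1). The knocked-out gene's transcript and the 20 gene lists fixed beforehand were therefore not analysed here, nor were the alternatives that concern them. Probes are named by identifier under a rule fixed before the data were examined. For each atg5 comparison and each treatment comparison in WT, these are the 2 largest rises and 2 largest falls among probes with an adjusted p under 0.05 and the same sign in both replicates. The rule was applied as fixed to the added comparison of Dehydration with ABA. The brightest probe stood for a locus. Larger called changes outside this rule were passed over. In WT the largest called fall had a log2 difference of -4.16 for Dehydration against ABA and -5.54 for Dehydration against Hydration. Among the 2892 loci with several kept probes, 1338 had a changed probe in Hydration, 600 in ABA, 816 in Dehydration and 680 in Rehydration. All probes changed in 692, 262, 408 and 206 of these, and probes changed in opposite directions in 9, 0, 0 and 3. Where a probe was not well above background on any array of a group, the fold is given as a lower bound. The bound sets the bright group's mean against the mean of, per array, the higher of the dim probe's own signal and the lowest signal well above background, after loess and Aquantile. Where the probe's own signal was the higher, as for Pp1s4_10V6.1 and Pp1s32_209V6.2, the bound equals the fitted fold. It concerns the dim signal only and takes no account of the SE.

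The fits were tested on simulated data with 200 changed probes among 19143. For atg5 versus WT in Hydration, the simulation recovered 86.6% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes, and 14 of 205 calls were false. For ABA against Hydration in WT, with 1 correlation for all spots, it recovered 5.97%, 49.3% and 90.9%, and 7 of 104 calls were false. When each probe had its own spread of ratio and of level, 38 of 150 calls in that comparison were false, so its adjusted p-values can be too small. The number of arrays limits the precision.

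Alternatives fixed beforehand were Agilent's processed signals, median centring in place of loess, quantile normalization, other filters on dim probes, the replicate block, an intensity trend with a robust prior, a 2-fold minimum and leaving out each array. In fits without 1 array the channel correlation was kept at its value from all arrays. An offset of 10, scaling to spike-in spots with a net signal of at least 100 on every array (3 probes per dye), and fits without the Rehydration arrays were added after the data were seen. For the spike-in probes, a first rule of well above background on every array left 1 probe in Cy3, and the net signal minimum replaced it after the spike-in values were seen. Computations used R 4.3.3, limma 3.58.1 and jsonlite 2.0.0, and figures Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.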

Results

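The data are 8 arrays on which WT and atg5 protonemata of Physcomitrium patens, the filamentous growth stage of the moss, were hybridised together. The 4 treatments (Hydration, ABA, Dehydration and Rehydration) had 2 arrays each. Abscisic acid (ABA) is the plant hormone of water stress, and ATG5 is needed to form autophagosomes, the vesicles that carry cell material to the vacuole. The share of gene spots well above background was 37.1 to 53.5% per channel on the Hydration, ABA and Dehydration arrays. It was 19.3 and 30.6% in WT and 29.2 and 23.4% in atg5 on the Rehydration arrays, replicate 1 first. No gene spot was saturated (0 on each array). Spots of 1 probe on 1 array had a median SD of 0.111 in the log2 ratio, and the 2 arrays of a treatment a median SD of 0.11. The arrays' identifiers are not paired with gene names, so genes are given by identifier.

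The comparison of atg5 with WT in well-watered colonies asks which transcripts differ between the atg5 line and WT without a stress. The labels name 1 knockout line, so the loss of ATG5 cannot be told apart from other differences between this line and WT. Pp1s33_372V6.1 was 64.2-fold higher in atg5 (log2 difference 6.0 ± 0.252 SE, n = 2, limma adjusted p = 2.7e-07). Pp1s80_148V6.1 was 54.8-fold higher (5.78 ± 0.161, adjusted p = 1.18e-07). Pp1s997_1V6.1 was 8.02-fold lower in atg5 (log2 difference -3.00 ± 0.173, adjusted p = 1.53e-06) and Pp1s73_255V6.1 was 6.79-fold lower (-2.76 ± 0.096, adjusted p = 5.51e-07). In all, 6261 of 19664 probes (5061 loci) differed, 3045 higher and 3216 lower. Of these 401 were at least 2-fold higher and 221 at least 2-fold lower. With the replicate number as a block 8630 probes differed, 4012 higher and 4618 lower. All 6215 of the 6261 probes that were measured on both arrays had the same sign on both, which their choice by the mean of these arrays largely fixes. The arrays correlated at 0.843 across probes, which are not independent replicates. The count was 2846 without replicate 1 and 3764 without replicate 2. With Agilent's processed signals it was 2233, with 660 higher and 1573 lower, and with median centring in place of loess it was 0 (2723 at an unadjusted p under 0.05). Without loess a dye bias stays in the ratios, with opposite sign on the 2 dye-swapped arrays of a treatment. The fit has no dye term, so such a bias enters the SE. For the 16 named atg5 differences the SE was 0.397 to 0.779, against 0.0915 to 0.259 with loess, at log2 sizes of 1.53 to 5.46. Counts of 0 with median centring, here and below, therefore do not show that the differences vanish.

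On ABA the same probes led the rises. Pp1s33_372V6.1 was 57.7-fold higher in atg5 (log2 difference 5.85 ± 0.252, n = 2, limma adjusted p = 3.87e-07) and Pp1s80_148V6.1 was 34.3-fold higher (5.10 ± 0.161, adjusted p = 1.86e-07). Falls were smaller. Pp1s77_124V6.1 was 2.96-fold lower (-1.57 ± 0.259, adjusted p = 0.00308, 0.0565 at -1.475 without ABA replicate 1, and 0.00145 to 1 over all alternatives), and Pp1s13_94V6.1 was 2.45-fold lower (-1.29 ± 0.0915, adjusted p = 1.3e-05). The probes Pp1s77_124V6.1 and Pp1s13_94V6.1 were not well above background in either genotype in Hydration. A total of 2645 probes (2145 loci) differed, 1685 higher and 960 lower, and 229 were at least 2-fold higher against 19 at least 2-fold lower. With the replicate number as a block 4589 probes differed, 2621 higher and 1968 lower. The count was 874 without replicate 1 and 760 without replicate 2, 331 (269 higher, 62 lower) with processed signals and 0 with median centring (168 at an unadjusted p under 0.05).

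In dried colonies Pp1s33_372V6.1 was 42.9-fold higher in atg5 (log2 difference 5.42 ± 0.252, n = 2, limma adjusted p = 5.35e-07) and Pp1s77_290V6.1 was 25.0-fold higher (4.64 ± 0.128, adjusted p = 6.29e-08). Pp1s80_148V6.1 was 33.1-fold higher (log2 difference 5.05) on replicate 1 alone. Its spot on replicate 2 was left out, so the naming rule passed it over. Pp1s81_151V6.1 was 2.42-fold lower (-1.27 ± 0.119, adjusted p = 5.71e-05), although in Hydration it was 2.07-fold higher in atg5 (1.05 ± 0.119, adjusted p = 0.00012). Pp1s100_32V6.1 was 2.34-fold lower (-1.23 ± 0.147, adjusted p = 0.000284, 0.000145 to 1 over all alternatives). With processed signals its log2 difference was -1.36 ± 0.815 (adjusted p = 0.523) and with median centring -1.53 ± 0.453 (adjusted p = 1). Altogether 3715 probes (2978 loci) differed, 2420 higher and 1295 lower, of which 343 were at least 2-fold higher and 25 at least 2-fold lower. With the replicate number as a block the count was 5851, with 3358 higher and 2493 lower. It was 1488 without replicate 1 and 1445 without replicate 2, 366 (323 higher, 43 lower) with processed signals and 0 with median centring (340 at an unadjusted p under 0.05).

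After rehydration the leading rises were smaller and other probes led the falls. Pp1s80_148V6.1 was 5.60-fold higher in atg5 (log2 difference 2.49 ± 0.161, n = 2, limma adjusted p = 1.99e-05) and Pp1s77_290V6.1 was 5.57-fold higher (2.48 ± 0.128, adjusted p = 4.58e-06). Pp1s22_377V6.1 was 6.32-fold lower (-2.66 ± 0.124, adjusted p = 3.04e-06), and was also lower in Hydration, by at least 1.45-fold (-0.58 ± 0.124, adjusted p = 0.00497). On ABA its difference was -0.18 ± 0.124 (adjusted p = 0.411). Pp1s11_295V6.1 was 6.12-fold lower (-2.61 ± 0.103, adjusted p = 1.22e-06) and was also lower in Hydration, by at least 2.48-fold (-1.37 ± 0.103, adjusted p = 7.23e-06), on ABA, by 1.70-fold, and in Dehydration, by 1.66-fold. Both probes were not well above background in atg5 in Hydration. In total 2832 probes (2375 loci) differed, 1381 higher and 1451 lower, with 117 at least 2-fold higher and 179 at least 2-fold lower. With the replicate number as a block 4352 probes differed, 2152 higher and 2200 lower. The count was 1665 without replicate 1 and 1101 without replicate 2, 3355 (1928 higher, 1427 lower) with processed signals and 0 with median centring (172 at an unadjusted p under 0.05).

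**Figure D1:**
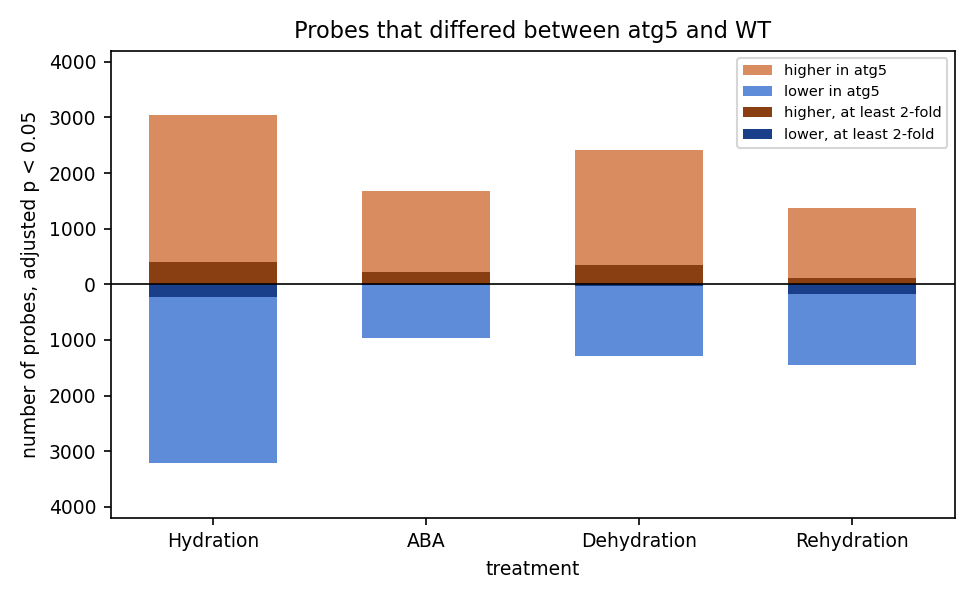
Number of probes (vertical axis) with an adjusted p under 0.05 between atg5 and WT in each treatment (horizontal axis), higher in atg5 above the line and lower below it, with the part that differed at least 2-fold in dark shades. In ABA and Dehydration the dark part lies nearly all above the line (229 against 19 and 343 against 25).

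**Figure D2:**
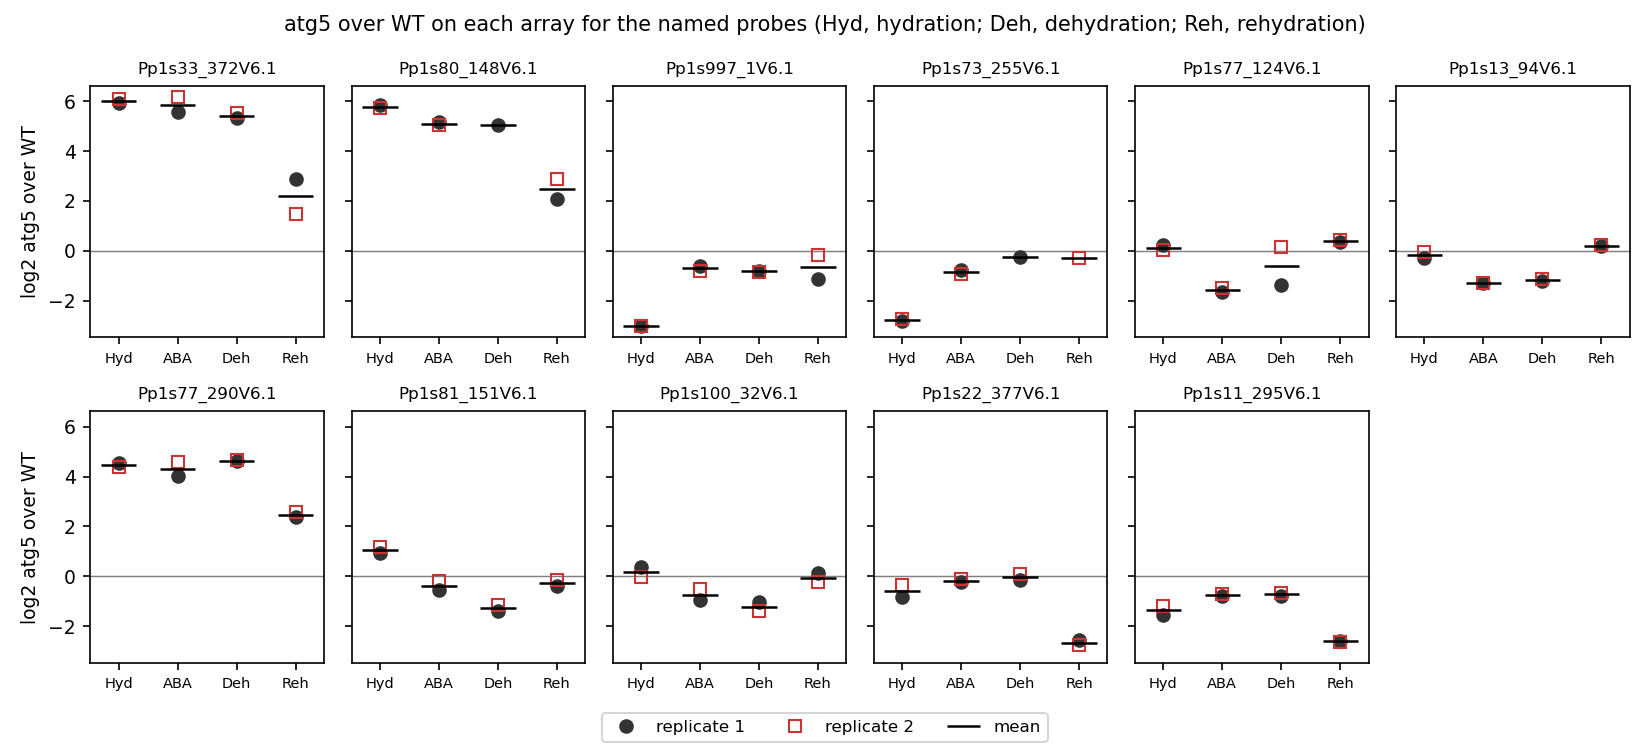
Log2 ratio of atg5 over WT (vertical axes) on each array for the 11 probes named for these comparisons, by treatment (horizontal axes), with circles for replicate 1, squares for replicate 2 and bars for the mean; a missing symbol is a spot left out. Pp1s33_372V6.1, Pp1s80_148V6.1 and Pp1s77_290V6.1 lie above 0 in all 4 treatments.

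Between treatments the atg5 effect was shared in part. Across probes, the mean effect in ABA correlated with that in Dehydration at 0.857 and with that in Hydration at 0.577, and the effect in Rehydration with that in Hydration at 0.222. These means pool same-numbered arrays, which share a slide and a dye orientation. With 1 treatment on 1 replicate and the other on the other, the correlations were 0.679 and 0.68, 0.48 and 0.459, and 0.163 and 0.167. The counts for independent lists given here leave the shared slides out of account too. Between ABA and Dehydration 1446 probes were higher in both (207 for independent lists) and 555 lower in both (63.2 for independent lists), and 4 changed in opposite directions. Between Hydration and Rehydration 477 were higher in both (214 for independent lists), 474 lower in both (237) and 502 opposite. In Hydration, ABA and Dehydration alike 978 probes were higher in atg5 and 285 lower, against 31.9 and 10.3 for independent lists. At least 2-fold in each of these 3 treatments were 134 probes, all higher in atg5, and 0 lower. By the mean ratio alone, with every spot measured, the split was 123 higher and 0 lower, against 303 and 55 with processed signals and 48 and 26 with median centring in place of loess. Median centring also shifted the tested probes down in these treatments, to median log2 ratios of -0.487, -0.163 and -0.171. Of the 978 and 285 probes, 313 and 74 changed the same way in Rehydration too.

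The difference of the atg5 effect between treatments was tested in the same fit. Against Hydration, the effect differed at 1763 probes in ABA (1028 higher and 735 lower), 2667 in Dehydration (1554 higher and 1113 lower) and 4413 in Rehydration (2191 higher and 2222 lower). With the replicate number as a block these counts were 3811, 4969 and 6770. Most of these probes passed the test of atg5 against WT in Hydration only, namely 1170 for ABA, 1487 for Dehydration and 2545 for Rehydration. Not passing in the other treatment does not show that the effect was absent there. In the same order, 220, 563 and 824 passed in the other treatment only, and 139, 257 and 502 in both with opposite signs. Passed or not, the estimated effects had opposite signs at 964, 1686 and 3018 of the probes. With Agilent's processed signals the counts were 116 (113 higher, 3 lower), 130 (122 higher, 8 lower) and 2248 (1652 higher, 596 lower), and with median centring 0, 0 and 0 (234, 306 and 1305 at an unadjusted p under 0.05). Without Hydration replicate 1 they were 590, 1129 and 2388, and without Hydration replicate 2 the first pair were 861 and 1481. For ABA the count was 629 and 785 without replicate 1 and 2 of ABA, for Dehydration 1306 and 1312 without those of Dehydration, and for Rehydration 2787 without its replicate 2.

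Between Dehydration and ABA the effect differed at 0 of 19664 probes in limma's test, with 1055 at an unadjusted p under 0.05. If no probe differed and the p-values were exact, 983 would be expected. This fit leaves out the pairing of same-numbered arrays, whose deviations correlated at 0.531 between these treatments. With the replicate number as a block it differed at 44 probes, with 2181 at an unadjusted p under 0.05, and without Dehydration replicate 1 at 2.

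The response of WT to ABA was led by transcripts not well above background in well-watered colonies. Pp1s4_10V6.1 was at least 442-fold higher on ABA (log2 difference 8.79 ± 0.235 SE, n = 2, limma adjusted p = 1.63e-09) and Pp1s32_209V6.2 at least 342-fold higher (8.42 ± 1.10, adjusted p = 0.000269). For both probes, here and below, the bound equals the fitted fold and leaves the SE out of account. Pp1s82_3V6.1 was 26.2-fold lower (-4.71 ± 0.274, adjusted p = 6.7e-07) and Pp1s346_19V6.1 was 21.9-fold lower (-4.45 ± 0.417, adjusted p = 2.28e-05). In WT 3810 of 19143 probes changed, 1578 higher and 2232 lower, and in atg5 4227, with 1878 higher and 2349 lower. With processed signals the balance turned, to 1737 higher and 1655 lower in WT and 2111 and 1857 in atg5. At least 2-fold were 794 higher and 863 lower in WT, and 958 higher and 958 lower in atg5. The WT count was 2417 without Hydration replicate 1 and 2431 without ABA replicate 1.

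Many of the probes that changed on ABA changed the same way in Dehydration. The labels do not state whether the dried colonies had been on abscisic acid before drying, so an effect of drying alone cannot be told apart. In WT, Pp1s32_209V6.2 was at least 476-fold higher in Dehydration than in Hydration (log2 difference 8.89 ± 1.10, n = 2, limma adjusted p = 0.000163) and Pp1s4_10V6.1 at least 370-fold higher (8.53 ± 0.235, adjusted p = 2.08e-09). Pp1s139_88V6.1 was 41.5-fold lower (-5.38 ± 0.837, adjusted p = 0.00082; well above background on 1 of the 2 Dehydration arrays) and Pp1s236_6V6.1 was 23.7-fold lower (-4.57 ± 0.586, adjusted p = 0.00021). In WT 4302 probes changed, 1865 higher and 2437 lower, and in atg5 4956, with 2375 higher and 2581 lower (2562 and 2222 with processed signals). The WT count was 2763 without Hydration replicate 1 and 2784 without Dehydration replicate 1. Directly between Dehydration and ABA, 277 probes differed in WT (189 higher and 88 lower in Dehydration) and 152 in atg5 (94 higher and 58 lower). With the replicate number as a block these counts were 562 and 342. The balance of higher and lower turned with the array left out. In WT it was 47 higher and 144 lower without Dehydration replicate 1 and 64 and 336 without Dehydration replicate 2, but 139 and 21 without ABA replicate 1 and 379 and 48 without ABA replicate 2. In atg5 it was 37 and 198, 45 and 221, 185 and 26, and 262 and 39 in the same order. Pp1s51_28V6.1 was 5.46-fold higher in Dehydration than on ABA in WT (2.45 ± 0.314, adjusted p = 0.00536) and Pp1s207_90V6.1 was 4.87-fold higher (2.28 ± 0.301, adjusted p = 0.0058; well above background on 1 of the 2 ABA arrays). Pp1s165_54V6.1 was 5.96-fold lower (-2.58 ± 0.308, adjusted p = 0.00437) and Pp1s363_23V6.1 was 4.70-fold lower (-2.23 ± 0.176, adjusted p = 0.000302). With processed signals the adjusted p of these 4 probes, in this order, was 0.0524, 0.107, 0.0559 and 0.0325, at log2 differences of 1.89, 3.94, -3.69 and -3.86. With spike-in scaling the adjusted p was 0.596 to 0.634, at 2.78, 3.65, -2.52 and -2.29. Over all alternatives, the 2-fold minimum included, it ranged from 0.000302 to 0.634. Without the Rehydration arrays the counts were 1084 and 759, and with processed signals 48 (25 higher, 23 lower) and 46.

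Both responses were set against the same Hydration channels, so their overlap lies above chance without any shared effect. In WT 1183 probes rose in both ABA and Dehydration (154 for independent lists), 1661 fell in both (284) and 4 went in opposite directions. The log2 changes correlated at 0.865 across probes, where 20 simulated data sets with no effect gave 0.498. Their covariance was 0.49 against 0.039 in the simulation. The Hydration arrays were also split 1 and 1, a choice made after the data were seen. Probes at least 2-fold higher on ABA in WT on 1 replicate changed by a median log2 of 1.06 and 1.27 in Dehydration on the other. Those at least 2-fold lower on ABA changed by -1.02 and -1.25. These values share no Hydration array, which argues against the shared arrays as the whole source of the overlap. The size of their part rests on the simulation.

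After rehydration WT differed from well-watered WT at more probes than on ABA or after drying. Pp1s4_10V6.1 was still at least 127-fold above Hydration (log2 difference 6.99 ± 0.235, n = 2, limma adjusted p = 1.39e-08), and Pp1s292_18V6.1 was 101-fold higher (6.66 ± 0.253, adjusted p = 3.45e-08). With spike-in scaling these log2 differences were 3.64 and 2.82. Pp1s248_61V6.2 was 116-fold lower than in Hydration (-6.86 ± 0.156, adjusted p = 1.26e-09) and Pp1s51_307V6.1 was 28.6-fold lower (-4.84 ± 0.518, adjusted p = 4.79e-05), both well above background on 1 of the 2 Rehydration arrays. In WT 6722 probes changed, 2829 higher and 3893 lower, and in atg5 6271, with 2720 higher and 3551 lower. In WT 865 probes were higher and 1319 lower both on ABA and after rehydration (233 and 454 for independent lists), with 227 opposite. These changes correlated at 0.561, against 0.503 in the simulation with no effect, and their covariance was 0.341 against 0.039.

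Set against the dried state, Pp1s391_57V6.1 was 46.4-fold higher in rehydrated WT (log2 difference 5.54 ± 0.308, n = 2, limma adjusted p = 7.91e-07) and Pp1s66_106V6.1 was 39.5-fold higher (5.30 ± 0.234, adjusted p = 4.3e-07). With spike-in scaling these log2 differences were 1.61 (adjusted p = 0.0338, lowest over all alternatives 7.3e-07) and 1.51 (adjusted p = 0.0534, lowest 1.37e-07). Pp1s248_61V6.2 was 50.9-fold lower (-5.67 ± 0.156, adjusted p = 2.34e-08), and Pp1s214_61V6.2 was at least 32.2-fold lower (-5.03 ± 0.243, adjusted p = 4.51e-07). In WT 6036 probes changed, 2830 higher and 3206 lower. In atg5 4454 changed, 1900 higher and 2554 lower, and Pp1s391_57V6.1 and Pp1s66_106V6.1 rose there by 23.0-fold and 19.1-fold (log2 differences 4.53 ± 0.308 and 4.25 ± 0.234, adjusted p = 6.83e-06 and 1.62e-06). The WT count was 3959 without Dehydration replicate 1 and 3913 without Dehydration replicate 2, and the atg5 count 2461 and 2657.

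These comparisons are relative to the bulk of the probes. Values relative to spike-ins assume the same sample RNA per spike-in in every labelling, for which the sources used here give 200 or 400 ng and no value per array. When channels were scaled to spike-in spots, the median log2 change of all probes from Hydration to Rehydration was -2.12 in WT and -0.37 in atg5. From Dehydration to Rehydration it was -1.92 in WT and -1.18 in atg5. The median change from Hydration was -0.78 in WT and 0.17 in atg5 on ABA, and -0.20 and 0.71 in Dehydration. The WT values rest in part on Hydration replicate 2, whose Cy5 spike-in signal was the lowest. For the bright probes the change relative to spike-ins in WT was 0.41 on replicate 1 and -0.68 on replicate 2 in Dehydration, and -0.40 and -1.6 on ABA, against 1.7 and 1.2, and 0.74 and 0.31, in atg5. This scaling moves all probes of a channel by 1 factor taken from 3 spike-in probes, so the splits it gives restate that factor and bear on no single probe. From Hydration to Rehydration 15692 of 15711 changed probes were lower in WT and 83 of 126 in atg5. From Dehydration to Rehydration 13469 of 13470 changed probes were lower in WT and 5008 of 5013 in atg5. On ABA 139 were higher and 429 lower in WT, and 213 higher and 22 lower in atg5. In Dehydration 264 were higher and 180 lower in WT, and 856 and 26 in atg5.

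**Figure D3:**
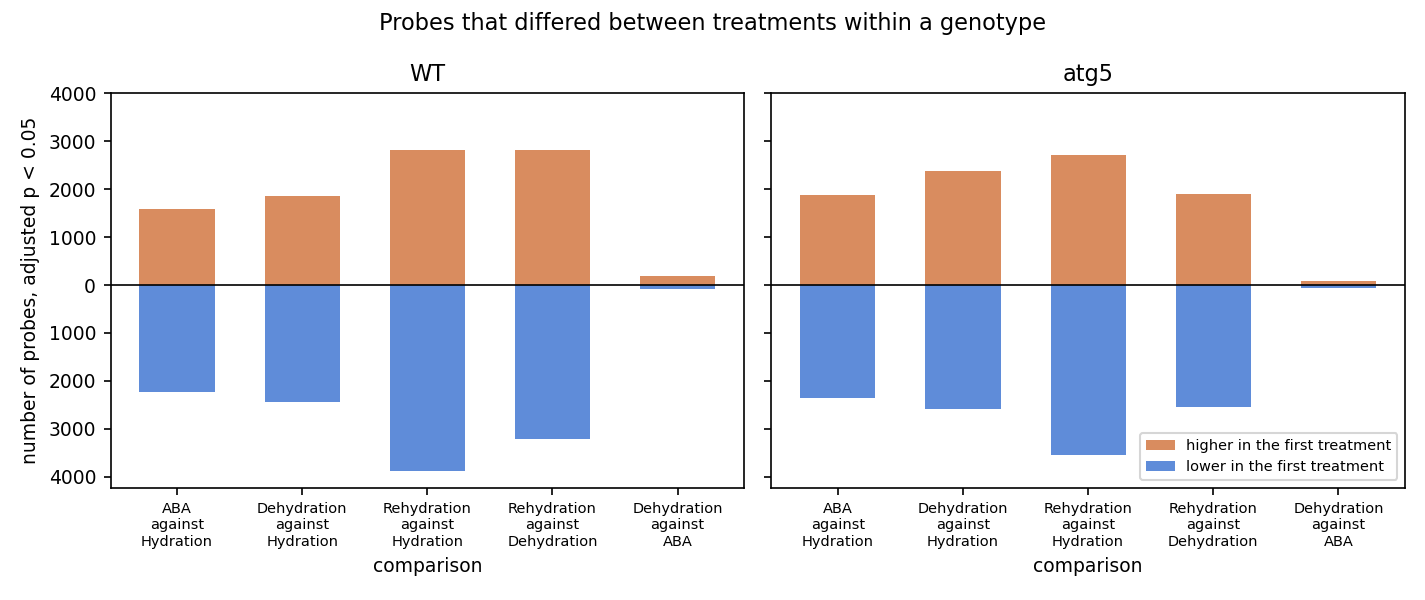
Number of probes (vertical axis) with an adjusted p under 0.05 between treatments within WT (left) and within atg5 (right), higher in the first-named treatment above the line and lower below it. Dehydration against ABA has the fewest, 277 in WT and 152 in atg5.

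The responses of the genotypes were compared at probes whose mean response over WT and atg5 reached 2-fold, a choice made after the data were seen. These probes also had a limma adjusted p under 0.05 for the response in WT, in atg5 or in both. Of 883 such probes that rose on ABA, the rise was larger in atg5 at 223 and smaller at 51 by the test of the difference, and 609 did not pass it. The median log2 rise was 1.52 in WT and 1.72 in atg5. Of 973 probes that rose in Dehydration, the rise was larger in atg5 at 272 and smaller at 80. Of 1135 that rose in Rehydration, it was larger in atg5 at 311 and smaller at 276, with medians of 1.54 in WT and 1.48 in atg5. Of 1488 that fell in Rehydration, the fall was larger in atg5 at 297 and smaller at 150. These splits rest on the tests of the difference, whose counts for ABA, Dehydration and Rehydration fell from 1763, 2667 and 4413 to 116, 130 and 2248 with processed signals, to 590, 1129 and 2388 without Hydration replicate 1, and to 0, 0 and 0 in limma's test with median centring (234, 306 and 1305 at an unadjusted p under 0.05).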

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

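The test on spike-in signal, with the spike-in probes it uses, was chosen after its result was seen, and the test on the brightest spots was decided by the highest in place of the lowest of its 4 differences after these were seen; the tests that replace loess by median centring were added after the other tests were seen.

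A difference between treatments stood out in 3 comparisons. By the test of the difference itself, the atg5 effect differed from that in Hydration at 1763 probes in ABA, 2667 in Dehydration and 4413 in Rehydration.

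The atg5 effect in Rehydration resembled that in Hydration less than the effect in ABA did: with Hydration on 1 replicate and the other treatment on the other, the correlation across probes was 0.48 and 0.459 for ABA and 0.163 and 0.167 for Rehydration. Spots near background on the Rehydration arrays were argued against as the whole cause. Among 5478 probes well above background in all 16 channels the difference in r was still 0.344 and 0.308, and the 2 Rehydration arrays correlated with each other at 0.855. These probes were still dimmer in Rehydration, with median log2 net signals of 5.94 to 7.30 per channel against 7.85 to 9.89 in Hydration. An effect of low signal as such therefore stays open. The normexp offset was argued against, since Agilent's processed signals, which have their own dye normalization, gave differences of 0.33 and 0.298 at those probes. With median centring in place of loess the difference in r between means of both replicates was 0.511, against 0.356 with loess. This cannot exclude loess, since a trend of the ratio with signal stays in median-centred means. The tested probes then had a median log2 ratio of -0.487 in Hydration, -0.163 in ABA and 0.0754 in Rehydration. A trend of like sign in Hydration and ABA only may itself widen the difference in r. A different effect of atg5 after rehydration is a hypothesis, and how the Rehydration colonies and their RNA were handled goes with the treatment and stays open.

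Spike-in RNA, which enters none of the planned comparisons, gave signal above the negative controls on each array. Its median net signal in Cy5 was lowest on Hydration replicate 2, at 58, where the negative controls had 8. Across the 10 spike-in probes the log2 ratio of Cy5 over Cy3 correlated between arrays at 0.94 to 0.998.

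The sample signal of the Rehydration arrays was low. Against Dehydration of the same replicate and dye, the median log2 signal of the bright probes changed by -2.97 and -3.41 in WT and -2.42 and -2.11 in atg5, and the mean log2 spike-in signal by 0.724, 0.794, 0.114 and 0.0825 in the same channels; against Hydration the sample changed by -3.45, -3.2, -1.52 and -1.24 and the spike-ins by -0.162, 1.68, -0.647 and -0.27. Poorer labelling, hybridization or scanning of a whole channel would lower both alike, which argues against it as the whole cause, though against Hydration it stays open for part of the smaller fall in atg5. The percent of signal in the 100 brightest spots, minus that on the highest other array of the replicate, was -11.2, -0.982, -1.42 and -5.79 over dyes and replicates. This cannot decide whether a few spots took most of the signal, since nonspecific signal in the total lowers the share on dim arrays. Negative controls on the Rehydration arrays had median net signals of 15 and 17.5 in Cy3 and 6 and 4 in Cy5. The gene spots had 21 and 24.5, and 15 and 9.5. A few spots taking most of the signal therefore stays open. Less mRNA per total RNA after rehydration stays open, as does a different amount or quality of sample RNA relative to spike-in in each reaction.

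Probes changed at least 2-fold in Hydration, ABA and Dehydration were nearly all higher in atg5, 123 against 0 by the mean ratio alone among probes with every spot measured. The normexp offset was argued against as the whole cause, since processed signals gave 303 higher and 55 lower (84.6% higher), although falls do appear there. Falls hidden near background were argued against as the whole cause. Among probes well above background in both channels of the 6 arrays, 90 were higher and 0 lower (100% higher). With processed signals 128 of such probes were higher and 7 lower. This selection leaves out probes whose fall takes atg5 to background, so hidden falls among those stay open. Loess stays open. Median centring in its place gave 48 higher and 26 lower (64.9% higher), between the bounds set for and against it. It also put the median log2 ratio of the tested probes at -0.487 in Hydration, -0.163 in ABA and -0.171 in Dehydration. That downward shift by itself adds falls and removes rises, so this split cannot decide on loess. Other differences between the 1 knockout line the labels name and WT, the loss of ATG5 itself and cross-hybridization between related genes were not tested.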

How the results depend on the processing

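The offset of 10, spike-in scaling, the fits without the Rehydration arrays and every setting of Dehydration against ABA were chosen after the data were seen. No alternative reversed any of the 36 named differences, and 15 of them were past the threshold under every alternative run. All 16 named atg5 differences lost their call with median centring, where a dye bias left in the ratios enters the SE of a fit with no dye term. Their log2 sizes stayed large (1.53 to 5.46, 8 larger and 8 smaller than with loess), and the SE rose from 0.0915 to 0.259 with loess to 0.397 to 0.779. Of the 18 counts, none moved by over 1.5 times with an intensity trend and robust prior, nor the 10 treatment counts with quantile normalization. The causes of the changes given here were not tested. A slide block was not run because it coincides with the replicate number, the authors' table because its values are the processed signals, and the gene list alternatives because identifiers carry no gene names. Fewer spots were well above background on the Rehydration arrays (19.3 to 30.6% per channel) than on the others (37.1 to 53.5%).

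For atg5 versus WT in Hydration, ABA, Dehydration and Rehydration, a 2-fold minimum left 622, 248, 368 and 296 probes, and for the differences of the effect against Hydration 348 (ABA), 447 (Dehydration) and 855 (Rehydration). Processed signals gave 2233, 331 and 366 in Hydration, ABA and Dehydration, and 116, 130 and 2248 for the differences. Median centring gave 0, 0, 0 and 0 in limma's test for the effects and 0, 0 and 0 for the differences, with 2723, 168, 340 and 172 and 234, 306 and 1305 at an unadjusted p under 0.05. Without a filter on dim probes the effect in ABA had 1630 probes and the differences for ABA and Dehydration 948 and 1646. Probes well above background on all arrays gave 2975 in Hydration, 2100 in Dehydration and 2642 for the Rehydration difference, from fewer probes tested. An offset of 10 gave 4172, 1194 and 1615 in Hydration, ABA and Dehydration and 469 and 871 for the ABA and Dehydration differences.

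With the replicate block the effects in Hydration, ABA, Dehydration and Rehydration had 8630, 4589, 5851 and 4352 probes. The differences against Hydration had 3811, 4969 and 6770, and the difference between Dehydration and ABA 44 (2181 at an unadjusted p under 0.05). Within a genotype same-numbered channels share slide, scan and dye, though their deviations correlated at 0.0349 to 0.105. There the block raised Dehydration against ABA to 562 in WT and 342 in atg5, and the other treatment counts by under 1.5 times, to 4491, 5043, 7644 and 6930 in WT and 4838, 5634, 7052 and 5334 in atg5.

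Between treatments a 2-fold minimum left 1657 (ABA against Hydration), 1862 (Dehydration against Hydration), 2739 (Rehydration against Hydration), 2383 (Rehydration against Dehydration) and 94 (Dehydration against ABA) in WT, and 1916, 2274, 2708, 1541 and 72 in atg5. Spike-in scaling gave 568, 444, 15711, 13470 and 0 in WT and 235, 882 and 126 for those against Hydration and 0 for Dehydration against ABA in atg5, these zeros with 1244 and 907 at an unadjusted p under 0.05. Dehydration against ABA had 427 and 256 without a filter, 48 and 46 with processed signals and 1084 and 759 without the Rehydration arrays, in WT and atg5.

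Leaving out 1 array of a treatment, with the other assumed to vary like the rest, gave 2846 to 3764 probes in Hydration, 760 to 874 in ABA, 1445 to 1488 in Dehydration and 1101 to 1665 in Rehydration. The differences had 590 to 861 (ABA), 1129 to 1481 (Dehydration), 2388 to 3140 (Rehydration) and 0 to 2 (Dehydration against ABA, 848 to 935 at an unadjusted p under 0.05). In WT the counts were 2417 to 2802 (ABA), 2763 to 3050 (Dehydration) and 4595 to 6766 (Rehydration) against Hydration, 3913 to 6096 for Rehydration against Dehydration and 160 to 427 for Dehydration against ABA. In atg5 they were 2910 to 3061, 3442 to 3579, 4250 to 6337, 2461 to 4873 and 211 to 301. For Dehydration against ABA most calls were lower in Dehydration without either Dehydration array and higher without either ABA array.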

Other observations

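The response classes and the test of the ABA hypothesis were chosen after the data were seen.

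Probes at least 2-fold higher on ABA than in Hydration in WT on 1 replicate were measured on the other. For the 1221 probes chosen on replicate 1, the median log2 difference from Hydration on replicate 2 was 1.2 on ABA and 0.607 after rehydration in WT, and 1.14 and 0.685 in atg5. For the 1100 chosen on replicate 2, it was 1.27 and 0.697 in WT and 1.34 and 0.778 in atg5 on replicate 1. For 1731 and 1633 probes at least 2-fold higher in rehydrated WT, the medians on the other replicate were 1.15 and 1.17 in WT and 0.819 and 0.778 in atg5. The choice was made in WT, which favours WT.

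The ABA-raised probes lay slightly lower in hydrated atg5 than in hydrated WT. Their median log2 ratio in Hydration was -0.0965 and -0.121, against -0.0329 and -0.0244 for all probes. Probes at least 2-fold lower on ABA lay lower as well, at -0.0873 and -0.0612, so the shift did not follow the direction of the response. The ABA-raised probes lay lower in atg5 on ABA (-0.0567 and -0.0286, against -0.0178 and 0.0124 for all probes) and in Dehydration (-0.0709 and -0.0392, against -0.0189 and 0.0107) too, though not in Rehydration (0.0126 and 0.0657, against -0.0132 and 0.0209), so the shift was not particular to hydrated colonies. For each of these lists in Hydration, ABA and Dehydration, 0% of 1000 random lists matched on mean signal over all arrays had a lower median. The lists were not matched on signal within a treatment, where raised and fallen probes differ in brightness. Random lists also treat probes as independent. The 0% therefore does not separate these shifts from a trend of the ratio with signal. One hypothesis was that hydrated atg5 colonies might already carry part of the WT response to ABA. Across probes, which are not independent replicates, the WT response to ABA on 1 replicate correlated with the atg5 effect in Hydration on the other at 0.00915 and -0.0253, which argues against it.

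Relative to spike-in signal, the fall in sample signal after rehydration was larger in WT than in atg5 in both dyes. Against Dehydration of the same replicate and dye the log2 change was -3.7 and -4.2 in WT and -2.54 and -2.19 in atg5. Against Hydration it was -3.28 and -4.88 in WT and -0.873 and -0.965 in atg5, where the -4.88 rests in part on the low Cy5 spike-in signal of Hydration replicate 2 (mean log2 7.74) and the -0.873 in part on the high one of Hydration replicate 1 (9.82). Both assume the same sample RNA per spike-in in every labelling, which the labels do not settle. With 2 arrays per treatment no test was made.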
